A study of Saccharomyces cerevisiae with 28 samples.

How the data were processed

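Footprint and mRNA libraries were deposited for each culture. Per the labels' protocols, cells were treated with cycloheximide, chilled over ice, frozen and lysed with glass beads. Lysate was digested with RNase for footprints, or used for total RNA that was depleted of ribosomal RNA, fragmented and size-selected, per the labels' protocols. Libraries were built by adapter ligation at the 3' end, reverse transcription, circularization and PCR, per the labels' protocols. Cycloheximide added before harvest can hold ribosomes near start codons, so footprint values can include that effect. Reads were aligned with TopHat to the yeast build sacCer3, per the submitters' processing notes, which also name DESeq without a role. Versions, the gene annotation, the counting rule, the use of strand and any filter are not given in the sources used here.

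The authors deposited RPKM values (reads per kilobase of gene, scaled to library size) in 4 tables, footprints and mRNA for SC and for YPA, each with 6692 genes and 1 column per library, not pooled. The authors also deposited TE as a linear ratio of footprint to mRNA RPKM for each SC culture, with 4773 genes, of which 4610 had all 8 values; the ratio columns are headed 4Gd where the sample titles say 4Gts. These ratios equalled the deposited footprint over mRNA RPKM to within 7.065e-12 on the log2 scale over 37852 values. A further ratio table for YPA was not used here. Gene names came from a RefSeq table by locus tag, which matched 6008 of 6692 genes and 4609 of the 4689 tested, and other genes keep the identifier of the files.

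Low RPKM values fell on whole multiples of 1 read once the gene length was shortened by 24 nt, a setting found from the values. Within 0.05 reads and up to 10 reads, 81.7% to 87.1% of low values in SC and 96.2% to 98.2% in YPA were whole. The depths given come from these steps. Because values are per gene and library and not all whole, no count test was run. The SC and YPA tables differ in which genes are listed at 0, for a reason not given: 371 genes were listed at 0 in all 12 YPA libraries, and 81 of them had a mean of at least 10 RPKM in SC mRNA. Tests were therefore made within the SC tables, and genes with near-identical copies, overlapping genes and antisense neighbours are uncertain where reads could be shared.

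The values were taken as log2(RPKM + 1), so differences of low genes are understated. Genes with a mean of at least 10 RPKM in both SC tables were kept (4689 genes; 4731 by the same rule in YPA; 4268 in both). Each library was scaled by the median ratio to the mean library of its table. log2 TE of a culture was scaled log2 footprints minus scaled log2 mRNA of the libraries whose titles give the same medium, strain, time and replicate. limma 3.58.1 in R 4.3.3 (lmFit and eBayes) was fitted to the 8 SC cultures with 1 mean per group, so that all 4 groups shared an estimate of the spread with 4 residual degrees of freedom (prior degrees of freedom 4.767 for TE and 2.672 for mRNA). The contrasts were 4Gts minus WT at 2 h, at 8 h and averaged, 8 h minus 2 h in each strain, and the change of the strain difference with time. Genes passed at a Benjamini-Hochberg adjusted p below 0.05. No replicate block was used, as the labels do not say what a replicate number shares. The range of TE was compared by an exact permutation test that exchanged strains within times.

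Of 29 gene lists, 27 had at least 4 tested members and were tested with camera at a preset correlation of 0.01, and the alpha-cell mating and meiosis lists were too small. camera was repeated with an estimated correlation, and fry, which asks whether a list moves one way on balance without setting it against other genes, was run beside it: 6, 3 and 6 lists passed fry for TE at 2 h, 8 h and averaged, and 3, 1 and 4 for mRNA. Adjusted p-values of lists are Benjamini-Hochberg values over the 27 lists of 1 comparison. The lists covered eIF4F and cap binding, other initiation factors, elongation and termination, cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, heat shock, general stress, galactose, Gcn4 targets, methionine, purines, glycolysis, respiration, the TCA cycle, the proteasome, histones, G1/S, G2/M, cell wall, ergosterol, iron, phosphate, autophagy, a-cell mating, invasive growth genes with reported internal initiation, and genes with regulatory upstream frames. In YPA, with 1 culture per strain and stage, no test was made. There a list's median was placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries.

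The genes named were set by rule: 20 preset genes; the 8 largest rises and 8 largest falls in TE and in mRNA of each strain contrast among genes past the threshold with no overlap between groups, or, where none passed, the 4 largest of each direction as values; up to 4 members past the threshold per list, otherwise 2 as values; and in YPA the 6 largest of each direction among genes with at least 10 RPKM in every library compared. Dubious and unnamed frames could be passed over as names and stayed in the counts. The design, the lists, this rule and most alternatives were fixed before the data were examined. The alternatives were the pseudocount (0.1 or 5 RPKM), the filter (none, or 50 RPKM), no scaling, quantile normalization, the authors' TE ratios, limma with trend and robust eBayes, 1 model over the 16 libraries, only the groups of a contrast, a replicate block, each culture left out, and 2 other list tests. Where 1 culture was left out of a group of 2, the lone culture was assumed to vary like the other groups. Averaging the 2 h and 8 h samples of a strain and number, taking strain and number as a random block, and leaving out hyphenated unnamed frames were added after the data were seen, as were the averaged footprint contrast and its alternatives.

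The limma step was tested on simulated values for 4689 genes with 100 changed genes per size. It recovered 70% of changes of 1 log2 unit and 99% of 2 for TE at 2 h, 94% and 100% for averaged TE, 7% and 71% for mRNA at 2 h and 64% and 98% for averaged mRNA, with 3.6% to 5.1% of calls false. camera called 0 of 100 unchanged simulated lists. The simulated noise was independent between genes and between cultures, which the data are not. With strain and number as a random block the correlation in the data was 0.462 for TE and 0.812 for mRNA. The rates of false calls therefore do not cover correlated genes or correlated cultures. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The planned comparison of genes with oligo-uridine runs in their leaders needs a genome sequence and was not run.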

Results

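Ribosome-protected mRNA fragments (footprints) and total mRNA were sequenced from the same budding yeast cultures of 2 strains. Per the labels, the series concerned cells depleted of eIF4G, the scaffold protein of the cap-binding complex eIF4F that joins mRNA to the small ribosomal subunit, with the strain 4Gts set against WT. No protein level was measured, so these data do not show whether eIF4G1 was lost. Yeast has 2 eIF4G genes, TIF4631 (eIF4G1) and TIF4632 (eIF4G2). The cells grew at 25 °C in raffinose, received galactose for 30 min and were then moved to 36 °C. In YPA medium 1 culture per strain was taken before the galactose and temperature change (pre-shift), at 0 h and at 2 h, which gave 6 cultures and 12 libraries. In SC medium 2 replicates per strain were taken at 2 h and at 8 h, which gave 4 groups, 8 cultures and 16 libraries. Translational efficiency (TE) was the footprint level of a gene over its mRNA level in 1 culture. Whole-read steps among the low RPKM values gave depths of 4.57 to 11 M reads for SC footprints, 3.9 to 18 M for SC mRNA, 1.35 to 5.61 M for YPA footprints and 1.7 to 3.28 M for YPA mRNA. At 10 RPKM a gene of 1 kb then has a counting error of 7.46% to 16% in SC mRNA, 9.52% to 14.8% in SC footprints and up to 27.3% in YPA footprints. The labels did not say whether the replicates, or the 2 h and 8 h samples of 1 strain and number, came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

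The targeted genes were examined first. TIF4632 mRNA was nearly missing from 4Gts: it measured 0.393 ± 0.158 RPKM (SD, n = 2) at 2 h and 0.241 ± 0.0422 at 8 h in SC, against 23.7 ± 2.98 and 24.7 ± 6.51 in WT. It fell by 4.18 on the log2(RPKM + 1) scale at 2 h (SE 0.23, limma, Benjamini-Hochberg adjusted p = 0.00258) and by 4.34 at 8 h (SE 0.23, adjusted p = 0.002), and that scale understates the change of a gene near 0. TIF4632 footprints were 0.946 ± 0.248 and 0.688 ± 0.096 RPKM in 4Gts against 48.5 ± 7.8 and 49.3 ± 8.78 in WT. In YPA the difference was already there before the shift, with TIF4632 mRNA at 1.29, 0.526 and 0.631 RPKM in 4Gts (pre-shift, 0 h, 2 h) and 82.7, 81.8 and 52.8 in WT. TIF4631 mRNA went the other way in SC: it was 214 ± 17.9 and 308 ± 138 RPKM in 4Gts and 67.4 ± 18.4 and 67.4 ± 13.5 in WT at 2 h and 8 h. Averaged over both times it rose by 1.87 (SE 0.30, limma adjusted p = 0.0266, n = 4 per strain), a call that none of the 8 fits without 1 culture kept (highest adjusted p 0.12) and that was lost when the 2 h and 8 h samples of 1 strain and number were averaged (adjusted p = 0.282). In YPA the TIF4631 mRNA levels were 286, 324 and 175 RPKM in 4Gts and 333, 174 and 208 in WT. The TIF4632 call at 2 h was lost without 4Gts 2 h replicate 1, 4Gts 2 h replicate 2 or WT 2 h replicate 2 (highest adjusted p 0.0696), and the calls at 8 h and over both times passed in all 8 such fits (highest adjusted p 0.0442 and 0.00553).

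UBR1, the ubiquitin ligase of the N-end rule pathway that removes proteins carrying a destabilising first residue, was measured as a gene used in degron systems. In YPA its mRNA was 47.6 RPKM in WT and 50 in 4Gts before the shift, and 1849 and 1749 at 0 h, after galactose. At 2 h it was 2476 RPKM in WT and 482 in 4Gts. In SC UBR1 mRNA was 1022 ± 437 and 815 ± 412 RPKM in WT (n = 2, 2 h and 8 h) and 211 ± 191 and 233 ± 172 in 4Gts. The averaged log2 difference of −2.27 (SE 0.59, n = 4 per strain) did not pass (limma adjusted p = 0.0672). URA3, a uracil synthesis gene and common strain marker, was at 10.9 ± 8.88 and 25.3 ± 1.03 RPKM in WT mRNA and 171 ± 15.6 and 133 ± 10.5 in 4Gts.

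**Figure D1:**
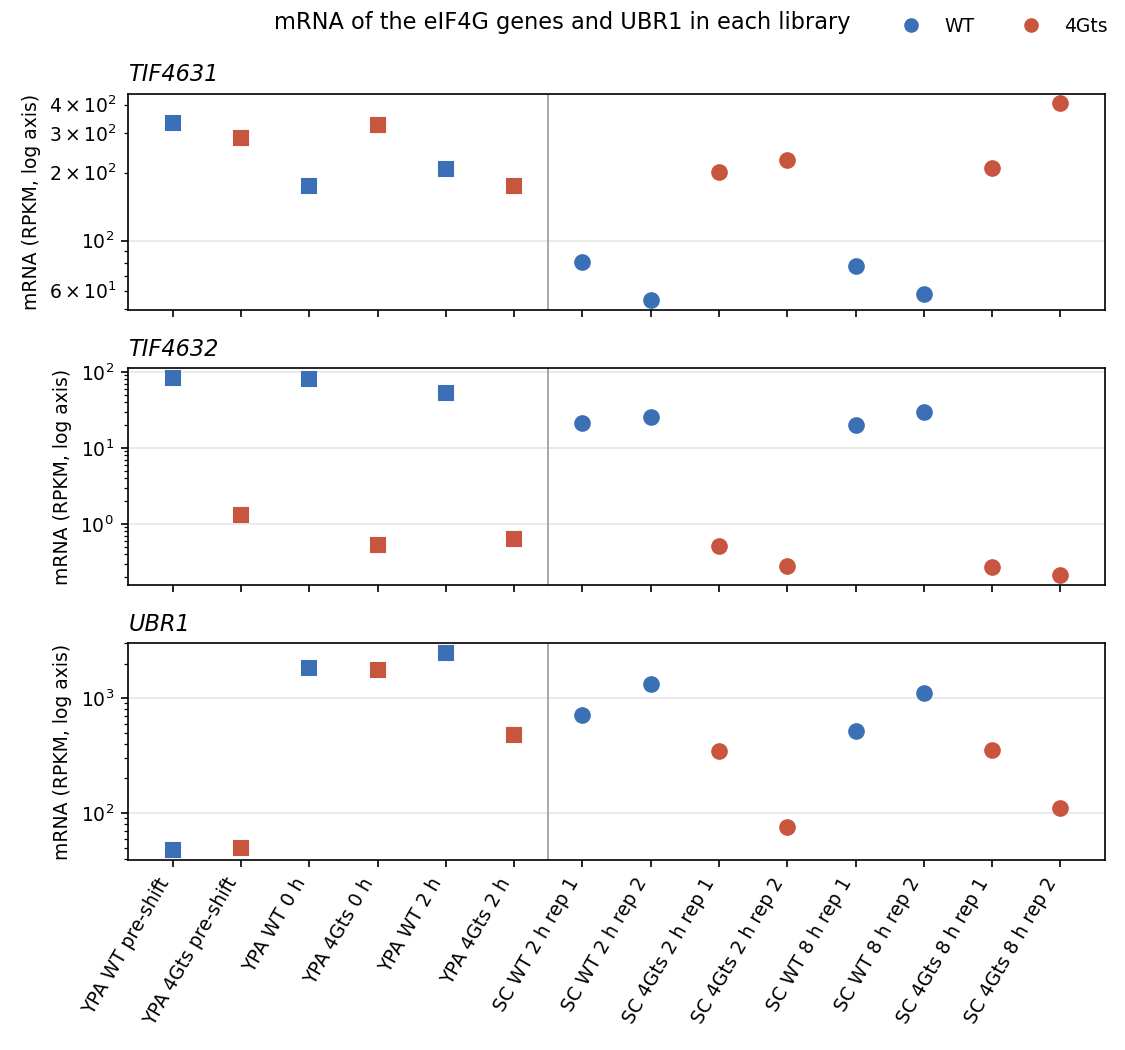
mRNA of TIF4631, TIF4632 and UBR1 in the 6 YPA and 8 SC mRNA libraries, RPKM on a log axis, with the YPA cultures as squares on the left and the SC cultures as circles on the right. TIF4632 lies between 0.526 and 1.29 RPKM in the YPA libraries of 4Gts and between 52.8 and 82.7 in those of WT, and UBR1 in WT goes from 47.6 before the shift to 2476 at 2 h.

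The main question of the design was which mRNAs lost or gained translation in 4Gts relative to other mRNAs. RPKM and the scaling remove any change of mRNA, footprints or TE that all genes share. A general fall in translation could therefore not be seen, and a rise or fall in TE is relative to the typical gene. At 2 h in SC, TE fell for 8 genes. CLN3, the G1 cyclin that sets cell size at Start, fell by 2.39 on the log2 scale (SE 0.32), and PCL5, a cyclin of the Pho85 kinase, fell by 2.31 (SE 0.30). MRPL4, a protein of the mitochondrial large ribosomal subunit, fell by 1.62 (SE 0.20), TIM23, the channel of the inner membrane translocase, by 1.45 (SE 0.20), MTO1, a mitochondrial tRNA modification enzyme, by 1.40 (SE 0.20) and DSF1 by 1.30 (SE 0.19). DSF1 mRNA was low in 4Gts at 2 h (2.978 and 3.853 on the log2 scale), and reads could be shared with its near relative MAN2. CLN3 kept its mRNA (291 ± 99.6 RPKM in 4Gts, 245 ± 81.8 in WT, n = 2) while its footprints were 9.06 ± 3.85 against 44 ± 25, and PCL5 mRNA was 198 ± 93.1 against 201 ± 60.1 with footprints of 8.78 ± 2.7 against 47.2 ± 0.0598. A fall here is a difference of 4Gts from WT, not a change after the shift. In YPA both genes already had fewer footprints for their mRNA in 4Gts before the shift, with 1 culture per strain. In all, 8 of 4689 genes passed with limma and Benjamini-Hochberg adjustment, 0 higher and 8 lower (lowest adjusted p 0.0473), and 952 had an unadjusted p below 0.05; the other 2 were the unnamed frames YPR108W-A and YGL088W, and YGL088W overlaps a small nucleolar RNA gene. The groups did not overlap for 52.3% of all genes, against 33.3% by chance with 2 cultures per group. Without 4Gts 2 h replicate 1 the count was 98, and without any other single culture it was 0, so each of the 8 calls passed in 1 of 8 such fits (highest adjusted p 0.245). The count of 0 higher and 8 lower was 0 and 6 on the deposited values without scaling, 4 and 5 on the authors' deposited TE values, and 0 and 0 with quantile normalization.

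At 8 h the same 2 cyclins had the lowest values, CLN3 at −1.93 (SE 0.32) and PCL5 at −1.77 (SE 0.30, both limma adjusted p = 0.198, n = 2), which did not pass. HAC1, the transcription factor of the unfolded protein response, was at −1.63 (SE 0.57, adjusted p = 0.384), and ERG29 and AIP5 were at 1.17 and 1.12 (adjusted p = 0.377). The unnamed frames YBR191W-A and YMR175W-A were at 1.72 and 1.67. With limma 0 of 4689 genes passed at 8 h, and 537 had an unadjusted p below 0.05. The groups did not overlap for 43.4% of all genes, against 33.3% by chance. Without 4Gts 8 h replicate 1 the count was 1.

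Averaged over 2 h and 8 h, which sets 4 cultures of 4Gts against 4 of WT, the largest falls in TE among named genes past the threshold were these. HAC1 fell by 2.25 (SE 0.40, limma adjusted p = 0.0253), CLN3 by 2.16 (SE 0.22, adjusted p = 0.00763), PCL5 by 2.04 (SE 0.21, adjusted p = 0.00763) and GCN4, the activator of amino acid synthesis genes, by 1.85 (SE 0.45, adjusted p = 0.0463). MLO1 and the alcohol dehydrogenase gene ADH5 each fell by 1.70 (SE 0.25 and 0.40). The largest rises among them were in RIO1, a kinase of small-subunit maturation (1.27, SE 0.26, adjusted p = 0.0354), BUD21, a small-subunit processome protein (1.23, SE 0.23, adjusted p = 0.0266), the prefoldin subunit YKE2 (1.20, SE 0.21, adjusted p = 0.024), AIP5 (1.10, SE 0.22), the glutaredoxin GRX7 (1.10, SE 0.16), the transcription elongation factor ELF1 (1.03, SE 0.22) and the peroxisomal protein PEX27 (1.02, SE 0.21). The mRNA of YKE2, AIP5, GRX7, ELF1 and PEX27 was lower in every 4Gts culture than in every WT culture. Log2 mRNA of YKE2 was 2.495 to 3.933 in 4Gts and 3.954 to 4.738 in WT, and that of GRX7 5.532 to 6.183 and 6.378 to 6.952. The TE rises of YKE2, AIP5, GRX7 and PEX27 thus mostly reflected lower mRNA, with little gain in footprints. That of ELF1 reflected lower mRNA only in part. The mRNA of RIO1 and BUD21 overlapped between the strains. The unnamed frames YFL032W, which overlaps HAC1, and YGL088W fell by 2.45 and 1.83, and YGL188C-A rose by 1.16.

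The mRNA of HAC1 and GCN4 was not lower in 4Gts. HAC1 mRNA was 2452 ± 297 and 2970 ± 973 RPKM in 4Gts at 2 h and 8 h against 1731 ± 120 and 1885 ± 151 in WT (n = 2), with footprints of 208 ± 74.3 and 590 ± 297 against 1149 ± 761 and 1212 ± 768. GCN4 mRNA was 1944 ± 122 and 1557 ± 157 against 1307 ± 75.4 and 1226 ± 152, with footprints of 15.3 ± 3.46 and 16.1 ± 4.29 against 68.9 ± 59.4 and 33.3 ± 18.3. The averaged GCN4 mRNA difference of 0.44 did not pass (limma adjusted p = 0.112). Of the genes set in advance, PAB1, which encodes poly(A)-binding protein, was at −0.54 in TE (SE 0.15, limma adjusted p = 0.063) and TIF4631 at −0.59 (adjusted p = 0.161). The TE of TIF4632, with under 1 RPKM in both layers in 4Gts, has no readable direction: it was at −0.56 (adjusted p = 0.116) with 1 RPKM added to each value and at 0.09 with 0.1 RPKM added. TE differences of TIF1 and TIF2, both encoding eIF4A, were −0.15 and −0.22, that of the eIF4E gene CDC33 was 0.02, and those of HSP104, HSP12, RPL3, RPS3, TEF1, HIS4 and PRE1 were 0.29, 0.25, −0.06, 0.12, −0.04, 0.08 and 0.09, with none past the threshold.

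**Figure D2:**
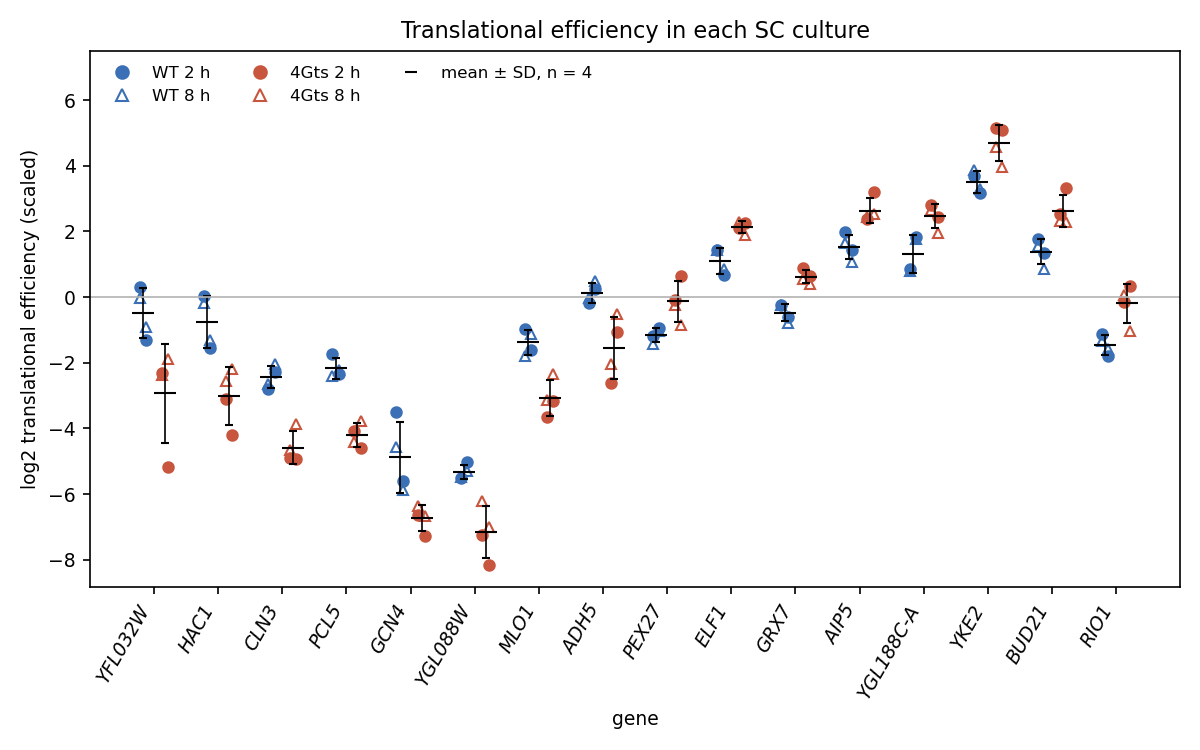
log2 TE in each SC culture for 16 named genes, circles for 2 h and triangles for 8 h, with the mean ± SD of the 4 cultures of each strain. CLN3 averages −4.59 in 4Gts and −2.44 in WT, and HAC1 averages −3.01 and −0.76.

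In total 343 genes changed in TE over both times, 121 higher and 222 lower (limma, Benjamini-Hochberg adjusted, 4 cultures per strain), and 1298 had an unadjusted p below 0.05. The 2 strains did not overlap for 327 of the 343, and for 21.6% of all genes, against 2.86% by chance if the 8 cultures were independent. The split was 114 higher and 136 lower on the deposited values without scaling, 120 and 143 with quantile normalization and 231 and 175 on the authors' deposited TE values. The count was 48 with no filter. In 1 model over the 16 libraries, which drops the matching by culture, 0 genes passed (lowest limma adjusted p 0.152). The count was 416 without 4Gts 2 h replicate 1, 100 without 4Gts 2 h replicate 2, 9 without 4Gts 8 h replicate 1 and 108 without 4Gts 8 h replicate 2. It was 2 and 19 without WT 2 h replicate 1 and 2, and 78 and 4 without WT 8 h replicate 1 and 2. CLN3 and PCL5 passed in all 8 of these fits (highest adjusted p 0.0475), HAC1 and RIO1 in 2 each and GCN4 in 1 (highest adjusted p 0.09, 0.121 and 0.116). MLO1 and YGL088W passed in 5, YKE2 and GRX7 in 4, ADH5, BUD21, AIP5, ELF1 and PEX27 in 2, YFL032W in 1 and YGL188C-A in 0. When the 2 h and 8 h samples of 1 strain and number were averaged first, 1 gene passed, PCL5 (adjusted p = 0.0423), with CLN3 at 0.124, HAC1 at 0.144, RIO1 at 0.144 and GCN4 at 0.189. With strain and number as a random block 9 genes passed, all lower, among them CLN3 (adjusted p = 0.0387) and PCL5 (adjusted p = 0.0462), with HAC1 at 0.0727.

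Of 71 measured genes for mitochondrial ribosomal proteins 67 were below 0 in TE, the median was −0.38, and 25 fell and 0 rose past the threshold over all genes, or 34 adjusted over the list alone. The group test, camera, gave an adjusted p of 2.13e-13 (n = 4 per strain), and adjusted p = 0.0736 with an estimated correlation. All list tests took the 8 cultures as independent. They were not repeated with the 2 h and 8 h samples of 1 strain and number as 1 unit, so their p-values may be too small. MRPL4 fell by 1.37 (SE 0.14, limma adjusted p = 0.00763), the small-subunit protein RSM7 by 1.16 (SE 0.15), IMG1 by 1.13 (SE 0.18) and MRP4 by 1.04 (SE 0.13). The group's median was −0.42 at 2 h and −0.37 at 8 h, and the camera call passed in all 8 fits without 1 culture at both times. With an estimated correlation it did not pass at either time (adjusted p = 0.112 at 2 h and 0.0646 at 8 h).

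Ribosome biogenesis genes, which make and assemble ribosomal subunits in the nucleolus, had a TE median of 0.24 over 118 members, with 11 higher and 1 lower, or 25 higher and 3 lower adjusted over the list alone (camera adjusted p = 1.63e-07, adjusted p = 0.617 with an estimated correlation). RIO1 rose by 1.27, NOP15 by 0.88 (limma adjusted p = 0.0345) and NOP6 by 0.73 (adjusted p = 0.0318), while the helicase gene DBP2 fell by 0.79 (adjusted p = 0.0484). Genes with regulatory upstream reading frames, where ribosomes meet short frames before the main one, had a median of −0.45 over 14 members, with 4 lower and 0 higher, or 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00256, adjusted p = 0.334 with an estimated correlation). The 4 were CLN3, GCN4, the arginine-regulated carbamoyl phosphate synthase gene CPA1 (−0.90, limma adjusted p = 0.0463) and SCO1 (−0.70, adjusted p = 0.0315). Targets of Gcn4 and other amino acid synthesis genes had a median of −0.22 over 48 members with 5 lower and 0 higher, or 6 lower adjusted over the list alone (camera adjusted p = 4.98e-05, adjusted p = 0.334 with an estimated correlation). They included CPA1, HOM3 (−0.88), HOM2 (−0.73) and ILV2 (−0.64). Glycolysis and ethanol genes had a median of −0.32 over 21 members with 1 lower, the phosphofructokinase gene PFK2 (−0.55), and 1 adjusted over the list alone (camera adjusted p = 0.00215, adjusted p = 0.663 with an estimated correlation). Without 4Gts 8 h replicate 2 that median was −0.20.

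These 5 of 27 lists passed camera for averaged TE, and each passed in all 8 fits without 1 culture. With an estimated correlation 0 of 27 passed. The same number, 5 lists, passed camera at 2 h and at 8 h, and 0 of 27 passed with an estimated correlation at either time. The glycolysis call at 2 h was lost without 4Gts 2 h replicate 2 or WT 2 h replicate 1 (highest adjusted p 0.1). At 8 h the glycolysis, Gcn4 target and ribosome biogenesis calls were lost without 4Gts 8 h replicate 2 (highest adjusted p 0.448, 0.0747 and 0.0747), and the upstream frame call without 4Gts 8 h replicate 1 (0.0989).

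The other TE lists did not pass camera, and single members moved within them. Cytosolic ribosomal proteins had a median of −0.01 over 137 members (camera adjusted p = 0.87), with RPL22B higher (0.85) and RPP0 lower (−0.70). Their median was 0.21 between the cultures numbered 1 and −0.22 between those numbered 2. Heat shock genes had a median of −0.01 (adjusted p = 0.457), with KAR2, STI1 and BTN2 higher (0.69, 0.63, 0.61) and the mitochondrial Hsp70 gene SSC1 lower (−1.03). In the eIF4F list (median −0.20, adjusted p = 0.131) the helicase gene DED1 fell by 0.57. TIF11 rose by 0.63 among the other initiation factors (median 0.05, adjusted p = 0.87) and the release factor gene SUP35 by 0.80 among elongation and termination factors (median −0.02, adjusted p = 0.909). Autophagy genes (median −0.07, adjusted p = 0.44) held ATG5 at −1.22 and ATG18 at −0.62, and G2/M genes (median −0.08, adjusted p = 0.332) held the chitinase gene CTS1 at −1.32 and ASH1 at −0.80. In ergosterol synthesis (median 0.08, adjusted p = 0.65) ERG2 and ERG11 rose by 0.66 and 0.61 and ERG26 fell by 0.58.

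In further TE lists 1 to 3 members passed. General stress genes had a median of −0.15 (camera adjusted p = 0.07), with MSC1 higher (0.74) and GAC1 lower (−0.62). The galactose regulon had −0.14 (adjusted p = 0.457) with PCL10 lower (−0.61), purine synthesis −0.22 (adjusted p = 0.114) with ADE13 lower (−0.61), and the respiratory chain −0.13 (adjusted p = 0.346) with ATP1 lower (−0.57). The TCA cycle had −0.15 (adjusted p = 0.0992) with LSC1 lower (−0.73), the proteasome 0.06 (adjusted p = 0.332) with PUP3 lower (−0.60), and histones −0.08 (adjusted p = 0.358) with HTZ1 lower (−0.76). The a-cell mating genes had a median of 0.12 (adjusted p = 0.44) with STE6 higher (0.54), and the invasive growth genes −0.24 (adjusted p = 0.44) with YMR181C lower (−0.94). G1/S genes had 0.06 (adjusted p = 0.87), with CLN3 lower. The rest, with no member past the threshold, were methionine metabolism (−0.29, adjusted p = 0.0992), cell wall (−0.23, adjusted p = 0.125), iron (−0.09, adjusted p = 0.751) and phosphate genes (0.02, adjusted p = 0.909). Median, mean and test differed in sign for elongation factors, cytosolic ribosomal proteins, heat shock, G1/S and phosphate genes.

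**Figure D3:**
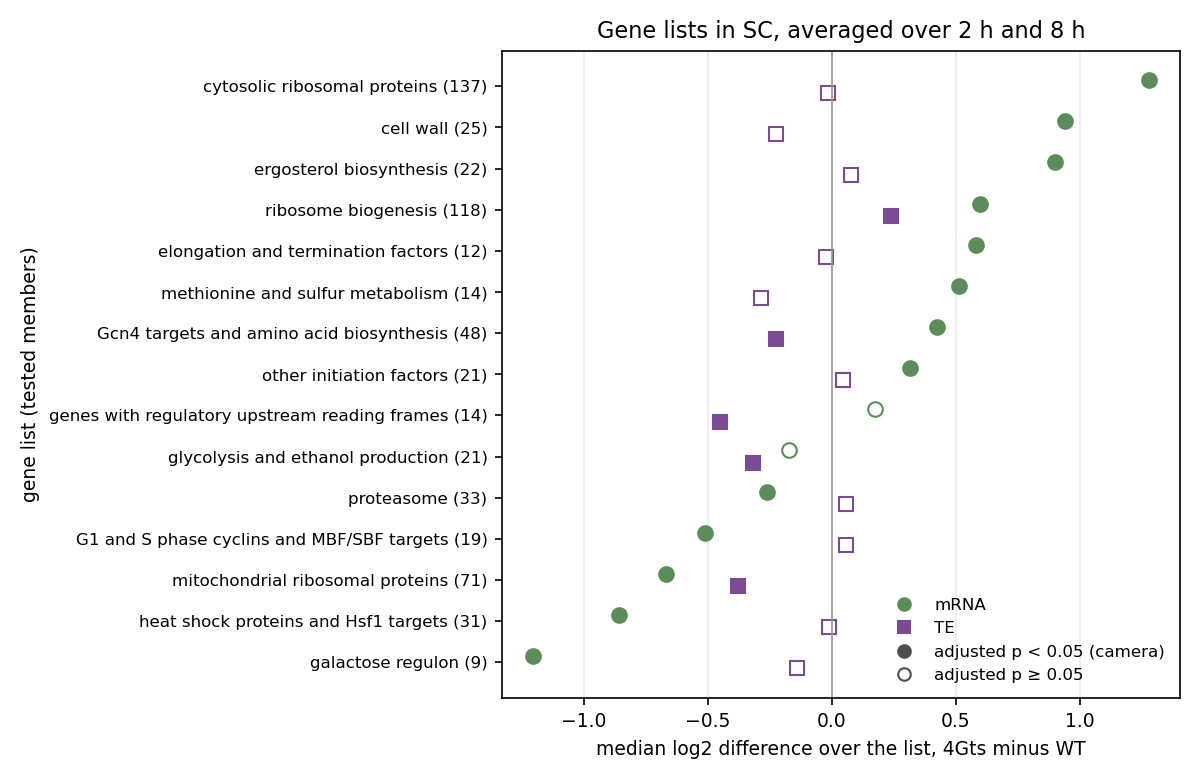
Median log2 difference, 4Gts minus WT, in SC averaged over both times, for each gene list that passed camera in TE or mRNA. Circles show mRNA and squares show TE, with filled symbols where the camera adjusted p was below 0.05. Lists that passed in neither are not drawn. Mitochondrial ribosomal proteins lie at −0.67 for mRNA and −0.38 for TE, and cytosolic ribosomal proteins at 1.28 and −0.01.

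The mRNA comparison asked which transcripts differed in abundance between the strains. At 2 h in SC the largest rises among genes past the threshold were URA3 (4.04, SE 0.55), the plasma membrane gene SFK1 (2.95, SE 0.35), the cell wall mannoprotein gene CWP1 (2.82, SE 0.25), ZPS1 (2.79, SE 0.39), YJL107C (2.78, SE 0.27), the drug efflux pump gene PDR5 (2.64, SE 0.38), MNC1 (2.57, SE 0.37) and BAG7 (2.56, SE 0.31). The limma adjusted p was 0.0344 for CWP1 and YJL107C and 0.0478 for the others. PHO84 (4.19) and YDR222W (3.33) did not pass at 2 h (adjusted p = 0.0641 and 0.0612), nor did HXT4 (adjusted p = 0.15), which lay between YDR222W and SFK1. Past the threshold after TIF4632, the next 7 falls were unnamed frames of the kind encoded by transposons, from −2.31 (YBL100W-A) to −2.27 (YDR210W-A), whose near-identical copies could share reads. Larger falls that did not pass were those of MAN2 (−4.20, adjusted p = 0.0762), ULI1 (−3.69, 0.059), DSF1 (−3.61, 0.126), RGI2 (−3.34, 0.225), EGO4 (−2.92, 0.118) and RGI1 (−2.70, 0.0669), among others. In total 33 genes changed, 19 higher and 14 lower, and 910 had an unadjusted p below 0.05; the split was 27 and 24 on the deposited values without scaling and 34 and 89 with quantile normalization. Groups did not overlap for 52.2% of all genes, against 33.3% by chance. The count was 0 without 4Gts 2 h replicate 1, 4Gts 2 h replicate 2 or WT 2 h replicate 2, 4 without 4Gts 8 h replicate 1 or 2, 2 without WT 2 h replicate 1, and 1 without WT 8 h replicate 1 or 2. CWP1 and YJL107C passed in 2 of these fits, URA3 in 1, and SFK1, ZPS1, PDR5, MNC1, BAG7 and the 7 frames in 0. At 8 h TIF4632 was the 1 gene that passed, with 470 at an unadjusted p below 0.05, and the count was 2 without 4Gts 8 h replicate 2.

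Averaged over both times, the phosphate transporter gene PHO84 rose by 3.70 (SE 0.52, limma adjusted p = 0.0187, n = 4 per strain), URA3 by 3.20 (SE 0.39), the hexose transporter gene HXT4 by 2.80 (SE 0.61), SFK1 by 2.78 (SE 0.25), YDR222W by 2.75, ZPS1 by 2.53 (SE 0.28), YJL107C by 2.48 (SE 0.19, adjusted p = 0.00789) and PDR5 by 2.46 (SE 0.27). Past the threshold after TIF4632, the falls were led by MAN2, a mannitol dehydrogenase gene (−3.90, SE 0.56, adjusted p = 0.0195), its near relative DSF1 (−3.23, SE 0.69), ULI1 (−3.16, SE 0.44), EGO4 (−2.53, SE 0.54), RGI1, induced in respiratory growth (−2.43, SE 0.34), the galactose permease gene GAL2 (−2.22, SE 0.48, adjusted p = 0.0489) and the copper transporter gene CTR1 (−2.14, SE 0.26). Reads could be shared between MAN2 and DSF1, so their falls may not be separate. GAL1 mRNA, at 553 ± 543 and 347 ± 345 RPKM in 4Gts against 1704 ± 315 and 1514 ± 133 in WT, differed by −2.36 without passing (adjusted p = 0.0917), as did GAL10 (−2.31, adjusted p = 0.101). The values of SSA4, HSP26, HSP104, HSP12 and CTT1 were −2.26, −1.98, −0.90, −0.40 and 0.27, those of RPL3 and RPS3 both 1.41, and those of TIF1, TIF2, TEF1, CDC33, PAB1, HIS4 and PRE1 0.95, 0.95, 0.59, 0.29, 0.12, 0.05 and −0.44, none past the threshold.

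In total 289 mRNAs changed, 127 higher and 162 lower (limma, Benjamini-Hochberg adjusted), and 1359 had an unadjusted p below 0.05. The strains did not overlap for 288 of them and for 26% of all genes, against 2.86% by chance if the 8 cultures were independent. The count was 6, 5, 5 and 104 without 4Gts 2 h replicate 1, 4Gts 2 h replicate 2, 4Gts 8 h replicate 1 and 4Gts 8 h replicate 2, and 6, 33, 1 and 1 without the WT cultures in the same order. TIF4632 passed in all 8 of these fits, YJL107C in 6, SFK1 in 4, URA3, ZPS1 and PDR5 in 3, ULI1 in 2, PHO84, MAN2, EGO4, RGI1 and CTR1 in 1, and HXT4, YDR222W, DSF1 and GAL2, like TIF4631, in 0. With the 2 h and 8 h samples of 1 strain and number averaged first, 0 genes passed (lowest adjusted p 0.0533), and with strain and number as a random block 1 passed, TIF4632 (adjusted p = 0.00148). Of 134 unnamed hyphenated frames, many of them transposon copies, 54 were lower, with a median of −0.90, and without these frames 121 genes passed, 78 higher and 43 lower. Both TE and mRNA changed for 38 genes, of which 16 had lower TE and higher mRNA, 13 had both lower, 7 had higher TE and lower mRNA and 2 had both higher. TE is computed from the same mRNA values, so error in mRNA alone pushes TE and mRNA in opposite directions. These counts therefore do not show a link between the layers.

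In mRNA the 137 cytosolic ribosomal protein genes were all above 0, with a median of 1.28 and 4 higher past the threshold over all genes, or 102 adjusted over the list alone (camera adjusted p = 4.57e-25, adjusted p = 0.638 with an estimated correlation). RPS29B and RPL4B rose by 1.58, RPS25B by 1.20 and RPS14B by 1.16. Of the 71 mitochondrial ribosomal protein genes 70 were below 0, with a median of −0.67 and 21 lower, or 57 adjusted over the list alone. MRPL50 fell by 1.51 (SE 0.19), MRPL39 by 1.23 (SE 0.16), and MRPL27 and MRPS5 by 1.17 (SE 0.16). This was the 1 list whose camera call (adjusted p = 1.46e-22) also passed with an estimated correlation (adjusted p = 0.0287). Both values took the 8 cultures as independent. Whether the call would stay with the 2 h and 8 h samples of 1 strain and number as 1 unit was not tested. Ribosome biogenesis genes had a median of 0.60, with 2 higher, TIF6 (1.21) and NOP10 (0.81), and 0 adjusted over the list alone (camera adjusted p = 8.5e-10, adjusted p = 0.77 with an estimated correlation). That median was 0.32 without 4Gts 8 h replicate 1. The call at 8 h (median 0.62) was lost without 4Gts 8 h replicate 1 (0.007, adjusted p = 0.973), and that at 2 h (median 0.60) without 4Gts 2 h replicate 1 (0.24, adjusted p = 0.065).

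In mRNA of the cell wall list 10 of 25 members rose and 1 fell, or 13 and 1 adjusted over the list alone, with a median of 0.94. CWP1 rose by 2.45 (limma adjusted p = 0.00789), TIR3 by 1.99, SLT2, the kinase of the cell wall integrity pathway, by 1.64, and CHS1 by 1.60 (camera adjusted p = 3.36e-07, adjusted p = 0.271 with an estimated correlation). In ergosterol synthesis 9 of 22 rose, or 14 adjusted over the list alone, with a median of 0.90. ERG5 rose by 1.91, HMG1 by 1.60, ERG25 by 1.50 and ERG11 by 1.36 (camera adjusted p = 1.86e-09, adjusted p = 0.339 with an estimated correlation). Heat shock genes had a median of −0.86 over 31 members with 3 lower, or 7 adjusted over the list alone (camera adjusted p = 1.01e-05, adjusted p = 0.691 with an estimated correlation). These were KAR2 (−1.76), HSP60 (−1.40) and SSC1 (−1.17). The list's median was −0.42 without 4Gts 8 h replicate 1 and −1.38 without 4Gts 8 h replicate 2. The galactose regulon had a median of −1.21 over 9 members, with GAL2 and GAL3 (−1.21) lower, or 7 adjusted over the list alone (camera adjusted p = 0.000286, adjusted p = 0.572 with an estimated correlation).

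In mRNA, Gcn4 targets had a median of 0.42 over 48 members with 2 higher, HIS3 (1.13) and LYS1 (0.77), and 2 adjusted over the list alone (camera adjusted p = 2.19e-05, adjusted p = 0.638 with an estimated correlation). Methionine genes had a median of 0.52 over 14 members with 3 higher, SAM1 (2.07), MUP1 (1.40) and SAM3 (1.37), and 3 adjusted over the list alone (camera adjusted p = 0.016, adjusted p = 0.608 with an estimated correlation). Elongation and termination factors had a median of 0.58, with 0 past the threshold and 5 adjusted over the list alone (camera adjusted p = 0.00219, adjusted p = 0.638 with an estimated correlation), and YEF3 and TEF4 stood at 1.66 and 1.17. G1/S genes had a median of −0.51, with TOS4 lower (−1.60) and 4 lower adjusted over the list alone (camera adjusted p = 0.00144, adjusted p = 0.375 with an estimated correlation). Without 4Gts 2 h replicate 1 or 4Gts 8 h replicate 1 that median was −0.31 or −0.28. The proteasome had −0.26, with 0 members past either threshold and RPN8 at −0.66 (camera adjusted p = 0.00352, adjusted p = 0.77 with an estimated correlation). That call was lost without WT 2 h replicate 1 or WT 8 h replicate 1 (highest adjusted p 0.0882), with a median of −0.13 in the first. Other initiation factors had 0.32, with TIF6 higher, 1 adjusted over the list alone (camera adjusted p = 0.048, adjusted p = 0.77 with an estimated correlation). That call was lost without 4Gts 2 h replicate 1, 4Gts 8 h replicate 1, WT 2 h replicate 2 or WT 8 h replicate 2 (highest adjusted p 0.398), with medians of 0.21, 0.12, 0.18 and 0.18, and the median was 0.50 without 4Gts 8 h replicate 2.

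Of 27 lists 13 passed camera for averaged mRNA, 12 at 2 h and 13 at 8 h. With an estimated correlation 1 list passed in each, the mitochondrial ribosomal proteins. Of the calls 11 of 13, 8 of 12 and 6 of 13 passed in all 8 fits without 1 culture. Those lost were, at 2 h, elongation factors, ribosome biogenesis, the proteasome and G1/S genes, without 4Gts 2 h replicate 1, WT 2 h replicate 1 or WT 2 h replicate 2 (highest adjusted p 0.213). At 8 h they were initiation and elongation factors, ribosome biogenesis, heat shock, Gcn4 targets, purine synthesis and histones, without 4Gts 8 h replicate 1 or WT 8 h replicate 2 (highest adjusted p 0.973). The remaining 14 did not pass camera over both times. Their medians were 0.56 for eIF4F (adjusted p = 0.326), −0.23 for general stress (0.124), 0.56 for purine synthesis (0.0576), −0.17 for glycolysis (0.5), −0.03 for the respiratory chain (0.583) and −0.39 for the TCA cycle (0.195). They were −0.37 for histones (0.0566), −0.26 for G2/M (0.119), 0.08 for iron (0.135), 0.34 for phosphate (0.124), −0.32 for autophagy (0.135), 0.55 for a-cell mating (0.228), 0.08 for invasive growth (0.668) and 0.18 for genes with upstream frames (0.967). Median, mean and test differed in sign for the invasive growth and upstream frame lists. Single members that passed were GSY1 (−1.37), NDE1 (0.79), ATP3 (−0.78), MDH1 (−1.32), HTA2 (−0.90), FET3 (1.35), FTR1 (1.11), ATG17 (−1.88), ATG5 (0.77), SCO1 (−1.17), PHO84, TIF4632 (−4.26) and TIF4631 (1.87), the last in both the eIF4F and the invasive growth list. The largest values among lists with none past were HXK1 (−1.70), GLK1 (−0.87), IMD4 (1.004), ADE6 (0.96), STE2 (1.48) and CLB2 (−0.77). The glycolysis median was −0.74 between the cultures numbered 1 and 0.34 between those numbered 2.

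Footprint levels combined both layers. TIF4632 footprints fell by 4.73 at 2 h (SE 0.28, limma adjusted p = 0.00895) and by 4.92 at 8 h (SE 0.28, adjusted p = 0.00702). UBR1 footprints differed by −2.76 and −1.68 (adjusted p = 0.187 and 0.528) and those of TIF4631 by 1.01 and 1.56 (adjusted p = 0.474 and 0.451). At 2 h 62 genes changed, 14 higher and 48 lower, with 920 at an unadjusted p below 0.05; the split was 1 and 1 on the deposited values without scaling and 2 and 1 with quantile normalization. The count was 1 without WT 8 h replicate 1 or WT 8 h replicate 2 and 0 without any of the other 6 cultures. At 8 h TIF4632 was the 1 gene that passed, with 547 at an unadjusted p below 0.05, and it was lost without 4Gts 8 h replicate 1 or 2 or WT 8 h replicate 1 or 2 (highest adjusted p 0.151). Averaged over both times 452 genes changed, 150 higher and 302 lower, with 1367 at an unadjusted p below 0.05; the split was 167 and 212 on the deposited values without scaling. The count was 1, 1, 78 and 261 without 4Gts 2 h replicate 1, 4Gts 2 h replicate 2, 4Gts 8 h replicate 1 and 4Gts 8 h replicate 2, and 4, 1, 1 and 1 without the WT cultures in that order. It was 0 with the 2 h and 8 h samples of 1 strain and number averaged first and 1, TIF4632, with strain and number as a random block.

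Comparing 8 h with 2 h asked whether translation went on changing at 36 °C. No gene passed in either strain: with limma 0 of 4689 genes passed for TE in WT (25 at an unadjusted p below 0.05) and 0 in 4Gts (167). For mRNA the counts were 0 in WT (3 at an unadjusted p below 0.05) and 0 in 4Gts (41). These fits took the spread between replicates as the error and did not pair the 2 times of 1 strain and number. In mRNA those 2 times were closer across genes (r 0.963 to 0.993) than replicates of a group (0.900 to 0.934). Changes with time smaller than the spread between replicates could be missed, so the counts do not show that none took place. For a change of the strain difference between the times 0 genes passed in TE (90 at an unadjusted p below 0.05, lowest adjusted p 0.0793) and 0 in mRNA (16). In TE 1 gene passed without scaling, with trend and robust eBayes, on the authors' ratios and with the number as a replicate block (lowest limma adjusted p 0.0186). It was 0 with quantile normalization, either other pseudocount, either other filter and 1 model over the 16 libraries. The TE counts for time in 4Gts and for the change in strain difference were 1 each without 4Gts 8 h replicate 1. The SD of log2 TE differences across genes was 0.46 between the strains at 2 h and 0.35 at 8 h, against 0.17 between 8 h and 2 h in WT and 0.26 in 4Gts.

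The range of TE across genes, from efficient to inefficient mRNAs, was compared between the strains. The SD of log2 TE over 4689 genes was 1.39 ± 0.066 in 4Gts and 1.28 ± 0.025 in WT (SD over cultures, n = 4), an excess of 0.11. The 2-sided exact permutation test within times gave p = 0.111, where 36 arrangements allow no p below 0.0556, so the design could not reach 0.05. The values in 4Gts were 1.43 and 1.44 at 2 h and 1.41 and 1.30 at 8 h, and those in WT lay between 1.26 and 1.31.

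The YPA series added the stages before the move to 36 °C (pre-shift, and 0 h after galactose at 25 °C), with 1 culture per strain and stage, so its differences had no replicate check. Before the shift 4Gts differed from WT in TE of HAC1 (−2.19), the metallothionein gene CRS5 (−1.76) and TIF4631 (−1.54), and on the positive side of DMO1 (1.80), MIN10 (1.70) and CMC4 (1.68). The unnamed frames YGR025W, YFR034W-A, YNL198C, YGL088W, YER088C-A and YHR073W-A were at 2.10, 1.69, 1.67, −2.03, −1.89 and −1.62. In mRNA the aquaporin gene AQY2 (1.58), the citrate synthase gene CIT2 (1.56), PHO89 (1.48) and ZRT1 (1.47) were higher in 4Gts, and the glycolytic genes TDH1 (−2.08) and ENO1 (−1.58), YGP1 (−1.91), DIA4 (−1.55) and PBI2 (−1.51) were lower. The mitochondrial ribosomal protein list had an mRNA median of −0.68 with 71 of 71 members below 0, outside all of 10000 random lists matched on expression, and a TE median of −0.03 (percentile 7.22), which was 0.11 on the deposited values without scaling. The eIF4F list had a TE median of −0.45 (percentile 0). Scaling moved the TE difference of all genes by 0.142 before the shift, 0.14 at 0 h and 0.068 at 2 h, and the values given are relative to it.

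At 0 h the TE differences in 4Gts were largest for the proteinase A inhibitor gene PAI3 (2.79), PEX34 (1.70) and ATG29 (1.52) on the positive side and for HAC1 (−2.29), MIN7 (−2.28), NFG1 (−1.86) and CWC21 (−1.83) on the negative side. For mRNA HPF1 and the zinc transporter gene ZRT1 were at 2.04, FCY2 at 2.01 and AAH1 at 1.93, against PAI3 at −2.65, the phosphatase gene PHO5 at −2.12, ADH2 at −2.06, RGI2 at −2.05, HAB1 at −1.94 and BDH2 at −1.84. Ribosome biogenesis had an mRNA median of 0.84 (percentile 100) and mitochondrial ribosomal proteins −0.58 (percentile 0). The TE median of mitochondrial ribosomal proteins was 0.11 (percentile 98.6), and that of cell wall genes was −0.39 (percentile 0).

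At 2 h mRNA of the small heat shock gene HSP26 was lower in 4Gts by a log2 difference of −6.04, EGO4 by −5.92, RGI1 by −5.02, TMA10 by −4.26 and the phosphoglucomutase gene PGM2 by −4.16. PRM5 (3.09), the glycine cleavage genes GCV2 (3.06) and GCV1 (2.70), ADE17 (2.99), YJL107C (2.74) and AQY2 (2.60) were higher. Heat shock genes had a median of −1.54 with 28 of 28 below 0, general stress genes −2.31 with 39 of 42 below 0, respiratory chain genes −1.69 with 39 of 39 below 0, the TCA cycle −1.39 and mitochondrial ribosomal proteins −1.21 with 71 of 71 below 0, all at percentile 0. Ribosome biogenesis had 1.03 with 132 of 132 above 0, the phosphate regulon 1.79 with 14 of 14, purine synthesis 1.06 and a-cell mating genes 1.23, all at percentile 100. The galactose regulon had −1.80 with 9 of 9 below 0. In TE, mitochondrial ribosomal proteins had −0.37 with 58 of 71 below 0 (percentile 0), genes with upstream frames −0.40 (percentile 0.19) and ribosome biogenesis 0.16 (percentile 99.9). HAC1 was at −3.60, NBL1 at −1.99, MRX7 at −1.97, ATG19 at −1.77 and DPI8 at −1.74, and the mitochondrially encoded ATP synthase gene OLI1 and the hexose transporter gene HXT7 at 2.34 and 1.89.

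**Figure D4:**
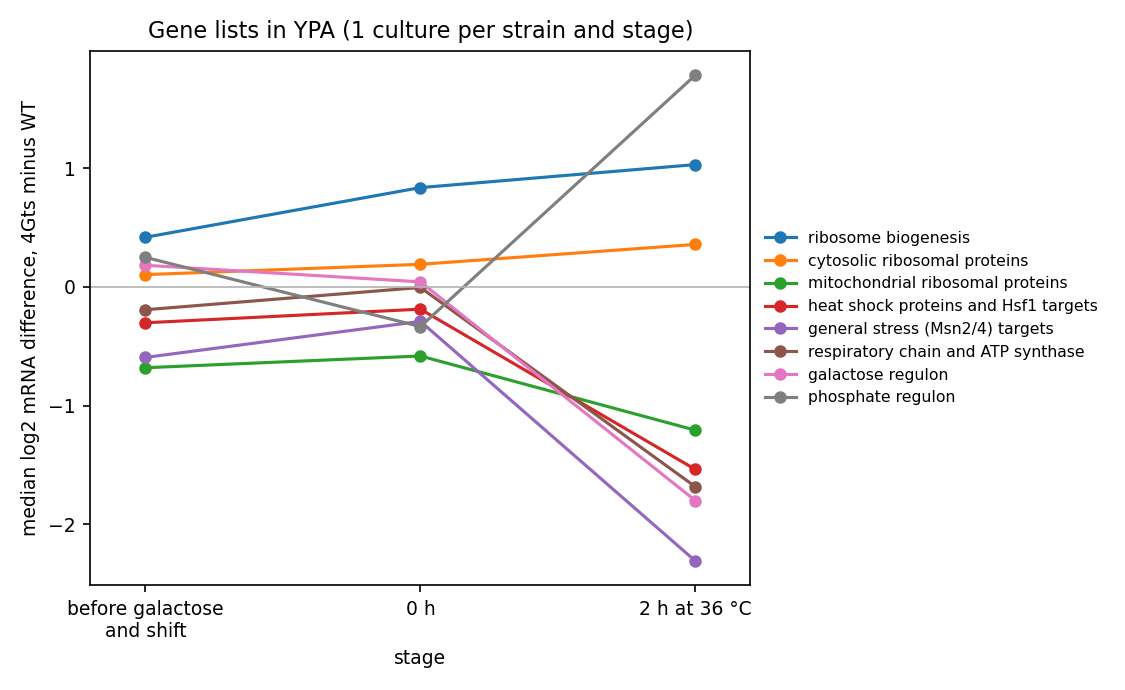
Median log2 mRNA difference of 4Gts from WT in YPA at pre-shift, 0 h and 2 h for 8 gene lists, 1 culture per strain and stage. Mitochondrial ribosomal proteins go from −0.68 to −0.58 and −1.21, and general stress genes reach −2.31 at 2 h.

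Within WT, 0 h was set against pre-shift, a step of 30 min in galactose at 25 °C with 1 culture per stage and no culture without galactose, so no cause can be assigned. GAL10 mRNA differed by 8.41 and GAL1 by 7.74, UBR1 by 5.24, RGI2 by 3.83, GCY1 by 3.64, FMP16 by 3.45, the membrane stress gene HSP12 by 3.11 and SOL4 by 2.92. AAH1 (−2.80), CGR1 (−2.54), URA7 (−2.53), the RNA polymerase I genes RPA190 and RPA135 (both −2.15) and NOP7 (−2.11) were lower. Ribosome biogenesis had a median of −1.53 with 132 of 132 below 0, cytosolic ribosomal proteins −0.81 and general stress genes 1.54 with 42 of 42 above 0. The galactose regulon had an mRNA median of 4.09 and a TE median of 0.77. TE of DBP2 and the nucleolin-like gene NSR1 differed by −2.63 and −1.59. From 0 h to 2 h the copper transporter genes CTR3 (3.86) and CTR1 (2.95), HSP26 (3.57), YRO2 (3.34) and AAH1 (2.89) were higher and the methionine genes MET6 (−3.38) and MET17 (−2.53), ADH2 (−3.03), PHO5 (−2.78) and BDH2 (−2.55) lower. Ribosome biogenesis had a median of 1.19 and methionine genes −1.46, and heat shock genes had a TE median of 0.54 with 27 of 28 above 0.

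In 4Gts, 0 h against pre-shift had GAL2 at 7.80, GAL10 at 6.78, GAL1 at 6.71, GAL7 at 6.68, UBR1 at 5.12 and HSP12 at 4.96. From 0 h to 2 h the cell wall stress genes PRM5 (4.30), SRL3 (2.94), PST1 (2.71) and SLT2 (2.67) and CIT2 (2.92) were higher, and the glycogen phosphorylase gene GPH1 (−4.62), RTC3 (−4.60), TMA10 (−4.60), PGM2 (−4.57), RGI1 (−4.54) and UBR1 (−1.99) were lower. General stress genes had a median of −2.48 with 41 of 42 below 0, against −0.68 in WT, and heat shock genes −1.35 with 28 of 28 below 0. Mitochondrial ribosomal proteins had −1.19 in mRNA and −0.43 in TE, and glycolysis genes had a TE median of 0.77. The difference between the strains in these time changes was not tested.

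The YPA and SC cultures shared no library, so the strain differences at 2 h could be set against each other across 4268 genes, which are not independent replicates. mRNA differences had a Pearson r of 0.622 and a Spearman rho of 0.612, footprints an r of 0.749 and TE an r of 0.276. Against the SC differences averaged over both times, 72.7% of all 4268 genes had the same sign in mRNA at 2 h, and 59% at 2 h and 61% before the shift in TE. Among the 205 genes selected because their mRNA changed in SC over both times, 95.6% had the same sign in YPA at 2 h (r = 0.891), and 86.3% had it before the shift (r = 0.669; over all genes 67.3%, r = 0.455). Among the 323 selected because their TE changed, 74.6% had the same sign at 2 h (r = 0.57), and 74% had it before the shift (r = 0.46). HAC1 TE was at −3.60 in YPA and −2.25 in SC over both times, and EGO4, RGI1 and YJL107C mRNA had the same sign in both media. GCN4 TE was at −0.59, −1.13 and −0.58 in YPA at the 3 stages. GAL1 mRNA was at −2.77 and UBR1 mRNA at −2.36 in YPA at 2 h, while the cytosolic ribosomal protein median was 0.36 in YPA and 1.31 in SC at 2 h (0.64 without WT 2 h replicate 2, 1.96 without WT 2 h replicate 1). Some genes with near-identical copies had values in SC but were listed at 0 in YPA, such as CUP1-1 and CUP1-2, each with a mean of 1853 RPKM in SC mRNA.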

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

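Of the tests in this part, the pre-shift test of mitochondrial ribosomal proteins was chosen after its result was seen, and the split of footprints was added after the count of 452 was seen, while the others were set before.

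In 2 unnamed reading frames the strains did not overlap at 2 h or at 8 h in SC, and the difference pointed opposite ways at the 2 times. Only the genes and lists named by rule were searched, and these frames were named for a large TE difference at 1 of the times. With 2 cultures per group the strains part by chance for 33.3% of genes at each time. No share over all genes was counted. The TE difference at 8 h minus that at 2 h was 3.36 for YPR108W-A and 3.32 for YBR191W-A on the log2 scale, and in mRNA it was −3.22 for YPR108W-A. The mean log2 TE of YPR108W-A was 1.21 and 2.37 in 4Gts at 2 h and 8 h against 3.65 and 1.45 in WT, and that of YBR191W-A was −2.30 and −0.16 against −0.70 and −1.88. The limma test of the change in strain difference did not pass (adjusted p = 0.0793, 0.9995 and 1).

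The 8 SC cultures can be parted into 4 and 4 in 35 ways, and in a model with the split and the time as terms, which differs from the one behind the 343, 289 and 452 genes, the real strain split called 536 genes in TE, 597 in mRNA and 763 in footprints. The highest other split called 11, 489 and 816. So 1 of 35 splits, the real one, reached the real value in TE and in mRNA, and 2 of 35 did in footprints. The splits with 489 and 816 genes were those by replicate number, which points to a structure of the samples. The 2 h and 8 h samples of 1 strain and number were correlated (0.462 in TE and 0.812 in mRNA with strain and number as a random block). The 8 cultures therefore do not count as independent. Only 3 splits keep these samples together, so the share cannot go under 0.05 and chance is not excluded by this test.

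The lower TE of mitochondrial ribosomal protein genes was set against abundance, length and a standing strain difference: among 10000 lists matched on footprint and mRNA level the median of −0.38 was at percentile 0, and the matched lists had a median of 0.051. Among lists matched on coding length it was also at percentile 0 (matched median −0.044), although the list is short, with a median of 714 nt against 1188 for all tested genes. Before the shift in YPA the list's median was −0.028 (95% bootstrap interval over members −0.096 to 0.062), and at 0 h, also at 25 °C, it was 0.106 (percentile 98.57 of matched lists), against −0.371 at 2 h in YPA. Neither early stage had a lower median like that at 2 h, but each is 1 culture per strain, the interval carries no spread between cultures, and scaling moved the pre-shift median from 0.113, so a strain difference present before the shift stays open. An effect of eIF4G loss on these mRNAs may remain as a hypothesis, and an effect of heat or slower growth in 4Gts stays open, as the design gives no 4Gts culture with eIF4G restored.

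TE differences of single genes before the shift in YPA went with those in SC, with r = 0.289 across 4268 genes that share no library. After regression on abundance and length, over the 4225 with a length, r was 0.218 (95% bootstrap interval 0.176 to 0.261), and without the 100 genes of largest SC difference it was 0.247 (interval 0.214 to 0.28; Spearman rho over all genes 0.299), so neither a trend with abundance and length nor a few extreme genes accounts for all of it. TIF4632 mRNA was already at 1.29 RPKM in 4Gts against 82.7 in WT before the shift, so a standing strain difference, in eIF4G2 or elsewhere in the genome, may be part of the SC differences. It cannot be separated here from an effect of depletion at 36 °C in those genes.

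The range of TE across genes was wider in 4Gts by an SD of 0.11 in SC and 0.063 in YPA. After the variance expected from read counting was taken off, 98.5% of the SC excess and 80.4% of the YPA excess were left (0.108 and 0.051), so depth does not account for most of it. The exact permutation test within times gave p = 0.111, where the design allows no p below 0.0556. A wider range caused by loss of eIF4G may be a hypothesis, and a strain difference unrelated to eIF4G stays open as untested.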

How the results depend on the processing

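Averaging the 2 h and 8 h samples, the random block, leaving out hyphenated frames and every alternative for averaged footprints were chosen after the data were seen. The other alternatives were planned. The cause was not tested unless one is given. Results are counts of genes past the limma threshold, with the reported count in parentheses. TE at 2 h (8): 41 with a pseudocount of 5 RPKM, 0 with no filter, where 6505 genes were tested, 20 at 50 RPKM or more, where 1694 were, 0 with quantile normalization, 35 with trend and robust eBayes, 0 in 1 model over 16 libraries, which drops the matching by culture, and 2 with only the groups of the contrast, which leaves fewer cultures. TE averaged (343): 48 with no filter, 90 at 50 RPKM, 0 in the 16-library model, 1 with times averaged, which leaves 4 values in place of 8, and 9 with the random block (consensus correlation 0.462 for TE, 0.812 for mRNA). mRNA at 2 h (33): 50 with a pseudocount of 5, 1 with no filter, 51 as deposited, 123 with quantile normalization, 3 with trend and 2 with only the groups of the contrast. mRNA at 8 h (1): 0 at 50 RPKM, where TIF4632 is left out, and 0 with only the groups of the contrast. mRNA averaged (289): 149 with no filter, 192 at 50 RPKM, 153 with trend, 0 with times averaged, 1 with the random block and 121 without hyphenated frames. Footprints at 2 h (62): 1 with no filter, 0 at 50 RPKM, 2 as deposited, 3 with quantile normalization and 0 with only the groups of the contrast. Footprints at 8 h (1): 0 at 50 RPKM, 2 as deposited, 0 with quantile normalization, 2 with trend and 0 with only the groups of the contrast. Footprints averaged (452): 151 at 50 RPKM, 0 with times averaged and 1 with the random block. TE over time in WT (0): 1 with the authors' TE ratios. Change of the TE strain difference with time (0): 1 as deposited, 1 with trend and 1 with the authors' ratios. Gene lists past the threshold (53 of 162): 3 with an estimated correlation and 23 with fry, which is another question. The TE range by interquartile range had an excess of 0.209 (exact permutation p = 0.0556). The mRNA r between YPA and SC at 2 h (0.622) was 0.716 at 50 RPKM. YPA genes with an mRNA strain difference of at least 1 log2 unit at 2 h (1086 of 4731) numbered 678 of 2336 at 50 RPKM.

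The replicate numbers are shared by both strains, but the labels do not say what a number shares, and with 2 numbers they count only as numbers. Deviations of same-numbered cultures had correlations of 0.14 to 0.603 in TE, 0.558 to 0.929 in mRNA and 0.68 to 0.961 in footprints. With the number as a replicate block the counts were 301, 3 and 850 for TE at 2 h, 8 h and averaged, 1266, 387 and 1845 for mRNA, 1525, 853 and 2142 for footprints, and 1 for the change of the TE strain difference with time; 62 lists passed.

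Leaving out each culture in turn, counts ranged from 0 to 98 for TE at 2 h, 0 to 1 at 8 h and 2 to 416 averaged, from 0 to 4 for mRNA at 2 h, 1 to 2 at 8 h and 1 to 104 averaged, from 0 to 1 for footprints at 2 h and at 8 h and 1 to 261 averaged, and from 0 to 1 for TE over time in 4Gts and for the change of the TE strain difference. Lists ranged from 53 to 66, and the TE range excess from 0.093 to 0.142. Among results with a call and YPA list medians the sign turned in 3, of which 2 were list medians without 1 culture. Sign changes of results without a call, such as that of TIF4632 TE, are counted among the 258 below. The pre-shift TE median of mitochondrial ribosomal proteins in YPA was 0.113 as deposited (−0.028 scaled). Without 4Gts 8 h replicate 1 the mRNA median at 8 h was −0.048 for other initiation factors (0.273 with it; highest 0.716) and 0.067 for heat shock genes (−0.709 with it; −1.464 without 4Gts 8 h replicate 2). Of the remaining values of named genes and lists 5260 kept their direction and side of the threshold or, untested, moved by at most 0.1 log2 or 0.05 in r, 650 lost and 193 gained the threshold, and 258 moved further or, without a call, changed sign; of the values of main comparisons 196 were within these bounds or within 1.5 times the reported count and 113 were not. The oligo-uridine leader alternatives were not run without a genome. Depth limits YPA most: at 10 RPKM a 1 kb gene has a counting error of up to 27.3% there.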

Other observations

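No test in this part was chosen after its result was seen. The count of genes listed at 0 and the values of unnamed frames are descriptions made after the data were seen.

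In YPA, 4Gts at 0 h was set against 4Gts at pre-shift, with 1 culture per stage, no replicate check and no culture without galactose. The median log2 change of ribosome biogenesis genes was −1.06 in mRNA, with 132 of 132 below 0, and −0.48 in TE, with 128 of 132 below 0. TE of DBP2, an RNA helicase gene, was at −2.83, the adenine deaminase gene AAH1 at −1.62 and the processome gene IMP3 at −1.50. mRNA of ECM1, KRR1 and UTP23, all ribosome assembly genes, was at −1.78, −1.78 and −1.74. RPC17, a subunit of RNA polymerase III, was at −2.06 in mRNA and 1.32 in TE. Mitochondrial ribosomal protein genes were at 0.53 in mRNA with 71 of 71 above 0 and at 0.19 in TE. General stress genes were at 1.76 with 42 of 42 above 0, and the galactose regulon at 4.10 in mRNA and 0.61 in TE. In WT over the same step, autophagy genes were at 0.91 with 15 of 15 above 0, respiratory chain genes at 0.42 with 39 of 39 above 0, and initiation factors outside eIF4F at −0.58 with 21 of 21 below 0.

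From 0 h to 2 h at 36 °C, TE of HAC1 was at 1.43 in WT, as its footprints went from 110 to 373 RPKM with mRNA at 1570 and 1983. In 4Gts HAC1 footprints were 39.7 and 47 RPKM with mRNA at 2553 and 2953. TE of the glutamine synthetase gene GLN1 was at −2.11 in WT, IZH2 at −2.09 and the antizyme gene OAZ1, whose translation needs a frameshift, at −1.78. Phosphate genes were at −1.26 in WT mRNA with 14 of 14 below 0, and at 0.69 in 4Gts with 14 of 14 above 0, a difference that was not tested. In 4Gts TE of the sulfiredoxin gene SRX1 was at 2.01 and HOT13 at 1.91, while PEX34 was at −3.04, ATG29 at −1.93 and PAI3 at −1.92. CLN3 footprints in YPA were 15.5, 26.8 and 25.2 RPKM in WT and 11.2, 18.2 and 9.03 in 4Gts (pre-shift, 0 h, 2 h), with mRNA of 70.3, 91.4 and 125 against 94.2, 122 and 135. PCL5 footprints were 27.8, 34.4 and 21.2 in WT and 11.5, 12.7 and 12.2 in 4Gts, with mRNA of 165, 222 and 152 against 173, 173 and 178. Both genes thus had fewer footprints for their mRNA in 4Gts at every stage, also before the shift.

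A hypothesis that mRNAs of low starting TE lose more TE in 4Gts was examined with WT pre-shift TE in YPA as the starting value. Its correlation across genes with the SC change was 0.013 (95% bootstrap interval −0.034 to 0.057), so starting TE in YPA showed no trend with that change. That value comes from another medium and temperature, and no SC culture was taken before the shift. The test therefore cannot decide the hypothesis for starting TE in SC, and it does not address the wider TE range of 4Gts. Longer coding regions did not lose more TE in SC, where log2 length and the averaged TE change had r = 0.094 (interval 0.064 to 0.124). In YPA, however, r was −0.094, −0.122 and −0.204 at pre-shift, 0 h and 2 h. Genes are not independent replicates in either test.

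The 2 h and 8 h mRNA libraries of 1 strain and number were closer (r across genes 0.963 to 0.993) than replicates 1 and 2 of a group (0.900 to 0.934). In YPA 371 genes were listed at 0 in all 12 libraries, and 81 of them had a mean of at least 10 RPKM in SC mRNA. In SC 35 genes were listed at 0 in all 16 libraries, and 0 of them reached that level in YPA. Of the 54 unnamed hyphenated frames with lower mRNA in SC, 21 were at 0 in every YPA mRNA library, and their median TE change in SC was 0.15, with 0 past the threshold.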
